A study of Homo sapiens with 5 samples.

How the data were processed

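The samples were RNA from HEY cells, a human ovarian carcinoma cell line, collected 48 h after transfection with a synthetic miRNA precursor. Samples were grouped by the treatment and replicate number in their labels: 2 received a miR-141 precursor at 30 nM and 3 received a negative control precursor, whose dose the labels do not give separately. The series design text counts 3 samples per group, and the third miR-141 sample was not analysed here. Per the labels' protocols, total RNA was amplified from the 3′ end of the transcripts, labelled with biotin and hybridized to Affymetrix U133 Plus 2 arrays, on which each gene is read by 1 or more probe sets.

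The deposited values are log2 signals per probe set, which the authors calculated with GCRMA, per the series design text. GCRMA corrects background by probe sequence, equalises the distributions of the arrays and summarises the probes of each set across arrays. The submitters' processing notes also name MAS5 and Affymetrix Expression Console, with versions not given in the sources used here, and the MAS5 present and absent calls were not used here. Because summarisation is done across arrays, a gene can have the very same value on several arrays: 2282 of the genes tested (26.3%) had equal values on 2 or more arrays and 129 on all 3 control arrays, which narrows their measured spread. No 2 arrays were copies of one another, since at most 816 of the 8673 genes tested had equal values on any pair. Normalization of this kind removes a shift shared by most genes, so differences are relative to the bulk of the array.

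Gene names came from the platform annotation (2016), updated by gene ID through a RefSeq gene table of assembly GRCh38.p14, which was used only for names. Of 54675 probe sets, 62 were array controls. Of the other 54613, 41091 had 1 gene symbol (41037 matched by gene ID and 54 kept under the array's symbol), 1801 had several and 11721 had none listed there. Probe sets with several symbols or none were not named. Probe sequences and their positions along the transcripts were not used here. The array's control probe sets of 1 further gene are not reported here.

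For each of the 19775 genes with a probe set, the probe set with the highest mean over the 5 arrays stood for the gene, and it was tested if its log2 value was at least 4 on at least 2 arrays, which left 8673 genes. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided, in R 4.3.3) without covariates, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of single genes come from this fit, except where the text names another setting, such as a fit without 1 array, over probe sets or with the mean of probe sets. An exact test of a single gene cannot go below p = 0.1 with 2 arrays against 3, so the calls rest on the spread that limma shares between genes (median SE 0.21, 5.53 moderated degrees of freedom). On simulated arrays with 200 of 8673 genes changed, the fit recovered 52% of changes of 1 on the log2 scale and 97% of changes of 2, with 5 false calls and 0 calls when none was changed. With 3000 genes changed, it recovered 89.7% and 99.7%, and 3.37% of calls were false. The simulated noise was normal and independent between genes, with the spread estimated by the fit and no shift of whole arrays. These rates therefore need not hold for the real arrays.

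The test, the named-gene rule, 20 gene lists and the alternatives were written before the data were examined. Lists with at least 5 tested members (16 of 20) were tested against the other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 16 lists, and again with the correlation estimated for each list. The estimated form takes its degrees of freedom from the arrays rather than the genes, so it has little power here. A call lost with it does not show that correlation between genes made a list or family pass. Counts of called members are also given adjusted over the list alone where they differ. The list of reported targets, drawn from general knowledge of miR-141 and miR-200a, was also set against 10000 random lists of the same size matched on mean signal in 10 bins. The genes named are the 15 with the largest decrease and the 12 with the largest increase among called genes without overlap between groups (uncharacterised loci, antisense genes and pseudogenes passed over), then ZEB1, ZEB2, CDH1 and VIM, then up to 4 tested members of each list with the largest absolute difference, 101 genes in all. Genes named outside this rule are marked as chosen after their values were seen.

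Alternatives were no filter, a filter at log2 6, the mean of a gene's probe sets, a test per probe set, quantile normalization or median centring of the arrays, eBayes with a trend or with robust estimation, array weights, a replicate block, an adjusted p under 0.10, a minimum difference of 1, camera with an estimated correlation, and leaving out each array in turn. With 1 miR-141 array left out, the lone array of that group is assumed to vary like the controls. The setting without genes whose probe sets were called in opposite directions was added after seeing the data. The planned comparison of genes with and without a miR-141 seed site was not run, because no 3′ UTR sequences were used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.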

Results

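Messenger RNA was measured on 5 arrays in HEY cells, a human ovarian carcinoma line, 48 h after transfection. The miR-141 group (2 arrays) received a precursor of miR-141, a member of the miR-200 family known for repressing the transcription factors ZEB1 and ZEB2, and the negative control group (3 arrays) received a control precursor. Between 27.9% and 28.8% of gene probe sets reached a log2 signal of 4 on each array, and the array medians lay between 1.42 and 1.47. Across probe sets, which are not independent replicates, arrays of a group correlated at 0.987 to 0.993 (4 pairs) and arrays of different groups at 0.953 to 0.971 (6 pairs). The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits their precision. Differences are log2 signal with miR-141 minus log2 signal with the negative control.

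The comparison asked which messenger RNAs differ when miR-141 is supplied to these cells. MYC, the transcription factor that drives growth genes, showed the largest decrease, from 10.5 ± 0.40 (SD, n = 3) in the controls to 3.36 ± 0.51 (SD, n = 2) with miR-141, a difference of −7.17 (SE 0.32, adjusted p = 0.0026). Large decreases were also called in the splicing regulator HNRNPL (−6.44, SE 0.27, adjusted p = 0.0023), the U5 spliceosome component SNRNP40 (−5.86), the splicing factor PRPF39 (−4.46), the mRNA export adaptor ALYREF (−4.41) and the translation initiation scaffold EIF4G1 (−4.15). Of 29 HNRNP and SRSF splicing factors, a family chosen after the results were seen, 4 rose and 5 fell. Their median was −0.23 (camera adjusted p = 0.18 over 26 families). CXCL8, which encodes the chemokine interleukin-8, fell by 5.63 (SE 0.35, adjusted p = 0.0026). The tetraspanin CD9 was at −4.63 and the matrix glycoprotein THBS1 at −4.47 (SE 0.64, adjusted p = 0.0071), both called. The remaining large decreases were in MIX23 (−4.44), TRIO (−4.31), EEIG2 (−4.23), MOB4 (−4.21), DCAF17 (−4.12) and the histone-binding protein RBBP4 (−4.07). For 6 of these 15 genes the miR-141 mean lay under the filter of 4, so the size of the fall there is set partly by background. With the mean of all probe sets of a gene the fall shrank for TRIO (−2.48), EIF4G1 (−1.47), THBS1 (−0.77) and RBBP4 (−0.72), all still called. THBS1 lost its call without miR-141 replicate 2 (adjusted p = 0.054).

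The largest increases were in genes that were near background in the controls. SCEL, which encodes the cornified envelope protein sciellin, went from 2.51 ± 0.41 (SD, n = 3) to 6.57 ± 0.09 (SD, n = 2), a difference of 4.06 (SE 0.26, adjusted p = 0.0029). GIT1, a regulator of ARF GTPases and focal adhesions, rose by 4.05 (SE 0.48, adjusted p = 0.0054), the lysosomal channel MCOLN3 by 3.89, the SMAD partner FOXH1 by 3.71, the zinc finger gene GLI4 by 3.53, the endosomal sorting gene HGS by 3.32 and the secreted guidance factor SEMA3F by 3.29. KIFC2, a kinesin, and SUV39H1, a histone methyltransferase, both rose by 3.21, and the DNA polymerase gene POLM and the cytoskeletal gene SPECC1L both by 3.18. PSMC3, a proteasome ATPase, showed a rise of 4.06 with wide error (SE 1.08, adjusted p = 0.033). In 10 of these 12 genes the control mean lay under 4. PSMC3 lost its call whichever of the 5 arrays was left out (adjusted p up to 0.18), HGS without either miR-141 array or control replicate 2 (up to 0.115), FOXH1 and SUV39H1 without either miR-141 array (up to 0.064), POLM without miR-141 replicate 1 (0.066) and GLI4 without control replicate 2 (0.057).

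Of 8673 genes tested, limma called 3326 (38.3%) at an adjusted p under 0.05, 1888 higher and 1438 lower with miR-141. More calls were higher than lower in that fit, but quantile normalization gave 1794 higher and 1665 lower, and without miR-141 replicate 1 there were 1099 higher and 1184 lower. The difference was at least 1 for 2181 of the 3326 (1181 higher, 1000 lower), and 60 genes were lower and 14 higher by at least 3. In 5604 genes (64.6%) the groups did not overlap, where chance gives 20%. The middle 18S ribosomal RNA control probe set, which reads RNA other than mRNA, also separated the groups, at 7.66 ± 0.32 (SD, n = 2) with miR-141 and 10.1 ± 0.28 (SD, n = 3) in the controls. The dimmer 18S sets were lower by 0.94 (3′) and 0.29 (5′) without overlap. Of the 28S sets, the middle one was lower by 0.48 with overlap, the 5′ one, under log2 4 on all arrays, was lower by 1.07 without overlap, and the 3′ one was at 0.05 with overlap. The 5′ difference rested mostly on control replicate 1, at 3.68 against 1.39 and 1.41 on the other controls. Spike-in controls were lower with miR-141 as well, by 1.11 for BioB (middle) and 1.00 for BioC (3′) without overlap, by 0.40 for BioDn (3′) with overlap, and by 0.10 for the brighter CreX (3′) without overlap. These gaps were narrow, since miR-141 replicate 2 and control replicate 3 nearly met. They read 10.33 and 10.34 for BioB (middle), 11.14 and 11.15 for BioC (3′). The 3′ and 5′ BioB sets overlapped. The number of calls fell to 1476 without miR-141 replicate 2, to 2116, 2174 and 2202 without control replicates 2, 1 and 3, and to 2283 without miR-141 replicate 1.

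**Figure D1:**
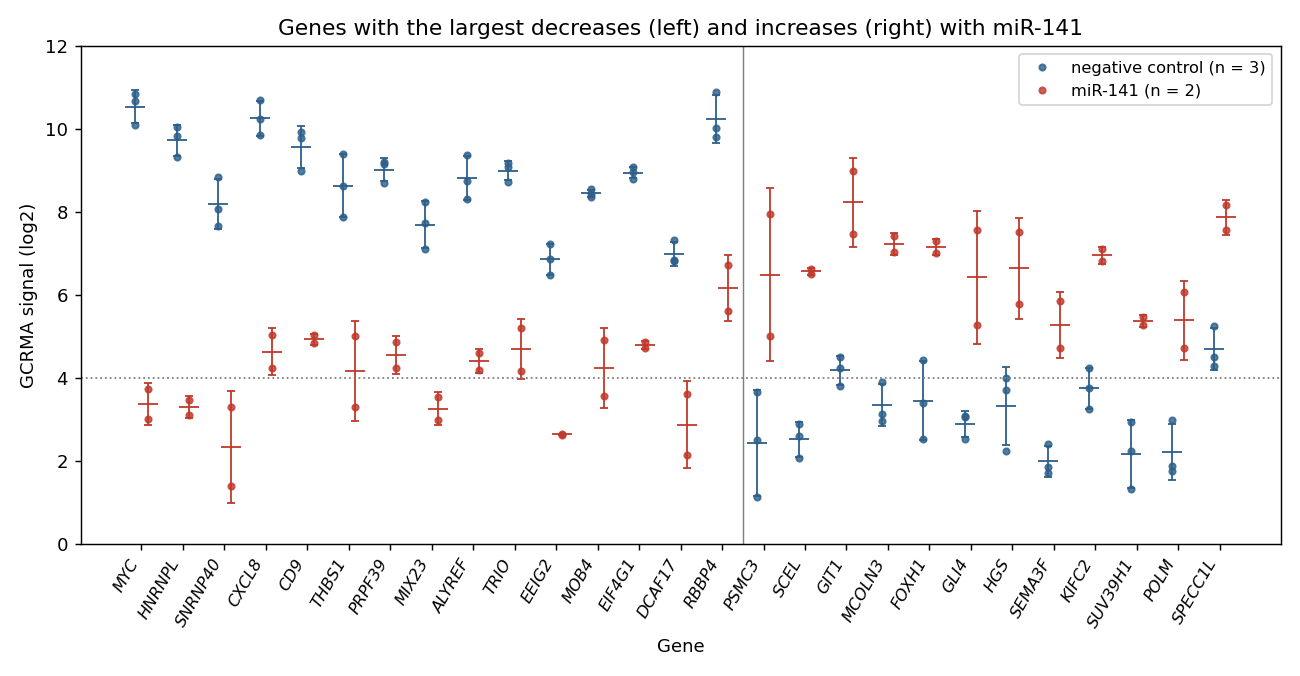
Log2 signal (vertical axis) of the 15 genes with the largest decreases and the 12 with the largest increases, with 1 point per array, a horizontal bar at each group mean and error bars of 1 SD (negative control n = 3, miR-141 n = 2); the dotted line is the filter at log2 4. The miR-141 points of MYC lie near 3.36 and its control points near 10.5, while SCEL runs the other way, from 2.51 to 6.57.

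Among the genes tied to the epithelial or mesenchymal state, ZEB1, the repressor of epithelial genes, fell from 9.96 ± 0.22 (SD, n = 3) to 8.86 ± 0.20 (SD, n = 2), a difference of −1.10 (SE 0.20, adjusted p = 0.011), and a dimmer ZEB1 probe set read −2.75 (−1.92 as the mean of both). ZEB2 was at −0.62 (SE 0.22, adjusted p = 0.078) and the intermediate filament gene VIM at −0.87 (SE 0.36, adjusted p = 0.11), neither past the threshold. A dimmer VIM probe set was called lower, at −2.68 (adjusted p over probe sets = 0.0024), the mean of both gave −1.77 (adjusted p = 0.0042), and the brighter probe set ran from −0.30 without miR-141 replicate 2 to −1.44 without miR-141 replicate 1 (adjusted p = 0.033). CDH1, which encodes E-cadherin, stayed under the filter on all 5 arrays, with a highest value of 1.19. Of 19 mesenchymal genes tested, 8 fell, 3 rose and 8 were not called. The fallers included SNAI2, a repressor of epithelial genes (−2.28, SE 0.14), the BMP antagonist GREM1 (−1.98) and the collagen cross-linking enzyme LOX (−1.52), while the microfibril gene FBN1 rose by 1.80 on the probe set used and was called lower, at −1.98, on another. Of members chosen after their values were seen, the transcription factors TWIST1 (−1.48) and TWIST2 (−1.35) and the fibronectin gene FN1 (−1.07) fell, COL6A1 (1.48) and TGFBI (1.16) rose, and CDH2, which encodes N-cadherin, was at 0.25, not called. As a list, the mesenchymal genes had a median of −0.64 and missed the threshold (camera adjusted p = 0.086, and adjusted p = 0.42 with an estimated correlation), and with no filter, over 30 genes, the median was 0.035. The median was −0.33 without miR-141 replicate 2, and the list passed with the mean of probe sets (adjusted p = 0.027) and without genes of opposite probe sets (0.029). Only 8 of 38 epithelial genes on the array passed the filter. Of these 3 rose, the keratins KRT7 (2.03) and KRT8 (1.28) and the splicing regulator ESRP1 (2.03), 2 fell, among them the desmosome gene PKP2 (−2.20), and 3 were not called (camera adjusted p = 0.94). Without miR-141 replicate 2, ZEB1 (adjusted p = 0.066), GREM1 (0.062), PKP2 (0.061) and ESRP1 (0.065) lost their calls, 5 mesenchymal genes were lower and no epithelial gene was called. KRT7, KRT8 and FBN1 lost theirs without miR-141 replicate 1. KRT8 also lost its call without control replicate 1 or 2, so of the fits without 1 array only that without control replicate 3 kept it.

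Among 27 genes reported elsewhere as targets of miR-141 or miR-200a, 6 fell, 5 rose and 16 were not called. The transcriptional coactivator YAP1 was lowest at −2.04 (SE 0.19, adjusted p = 0.0039), with its other probe sets at −0.58 and 0.03, neither called, and −0.87 as the mean of its probe sets (adjusted p = 0.024). The receptor tyrosine kinase EPHA2 (−1.62), the bromodomain gene BRD3 (−1.44) and the deacetylase SIRT1 (−1.31) fell too. The list median of −0.19 lay at percentile 5.55 of 10000 matched random lists (two-sided permutation of list membership among genes of like signal, p = 0.11), and camera gave an adjusted p of 0.30. The medians of the random lists centred on 0.087 rather than 0. EPHA2 lost its call without miR-141 replicate 2 (adjusted p = 0.051), where 3 members were lower. Higher members numbered 2 without any 1 of the arrays except control replicate 1, where they numbered 3.

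Of 23 target genes of the coactivator YAP tested, 8 fell, 2 rose and 13 were not called, with a median of −0.65. As a list they were lower by camera, with an adjusted p of 0.016 at the preset correlation, and not with an estimated correlation (adjusted p = 0.42). The RNA-binding protein gene RBMS3 fell by 2.07 (SE 0.28, adjusted p = 0.0064) and F3, which encodes tissue factor, fell by 1.74 (SE 0.23, adjusted p = 0.0062), while IGFBP3, a binding protein of insulin-like growth factors, rose by 1.11 and FJX1 was at −1.27 (adjusted p = 0.10). Chosen after their values were seen, AJUBA (−1.06) and CCN2 (−0.92), a classic YAP target, were also called lower and CCN1 was at −0.24, not called. The list's call also ended with the mean of all probe sets of a gene (adjusted p = 0.072) and under the stricter filter (0.078), and without 1 array the median ran from −0.43, with 6 lower members (miR-141 replicate 2 left out), to −0.82, with 12 (miR-141 replicate 1).

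Of 26 hypoxia and glycolysis genes tested, 10 rose, 1 fell and 15 were not called, with a median of 0.49. As a list they were higher by camera, with an adjusted p of 0.037 at the preset correlation, and not with an estimated correlation (adjusted p = 0.42). The lipase inhibitor ANGPTL4 rose by 2.32 (SE 0.31, adjusted p = 0.0064), the stress gene NDRG1 by 1.89 (SE 0.32, adjusted p = 0.010), the enolase gene ENO2 by 1.41 and the glucose transporter SLC2A1 by 1.38. Of members chosen after their values were seen, the angiogenic factor VEGFA rose by 1.38 and the kinase PDK1 by 1.33, the collagen hydroxylase P4HA1 fell by 1.04, and the core glycolytic genes PGK1 (−0.06), LDHA (0.26) and ALDOA (0.38) were not called. The list's call ended without miR-141 replicate 1 (adjusted p = 0.093, 6 members higher), without control replicate 3 (0.059) and under the stricter filter (0.11). The median was 0.24 without miR-141 replicate 1 and 0.83 without miR-141 replicate 2. ANGPTL4 and NDRG1 lost their calls without either miR-141 array (adjusted p up to 0.083) and ENO2 without miR-141 replicate 1 (0.070).

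**Figure D2:**
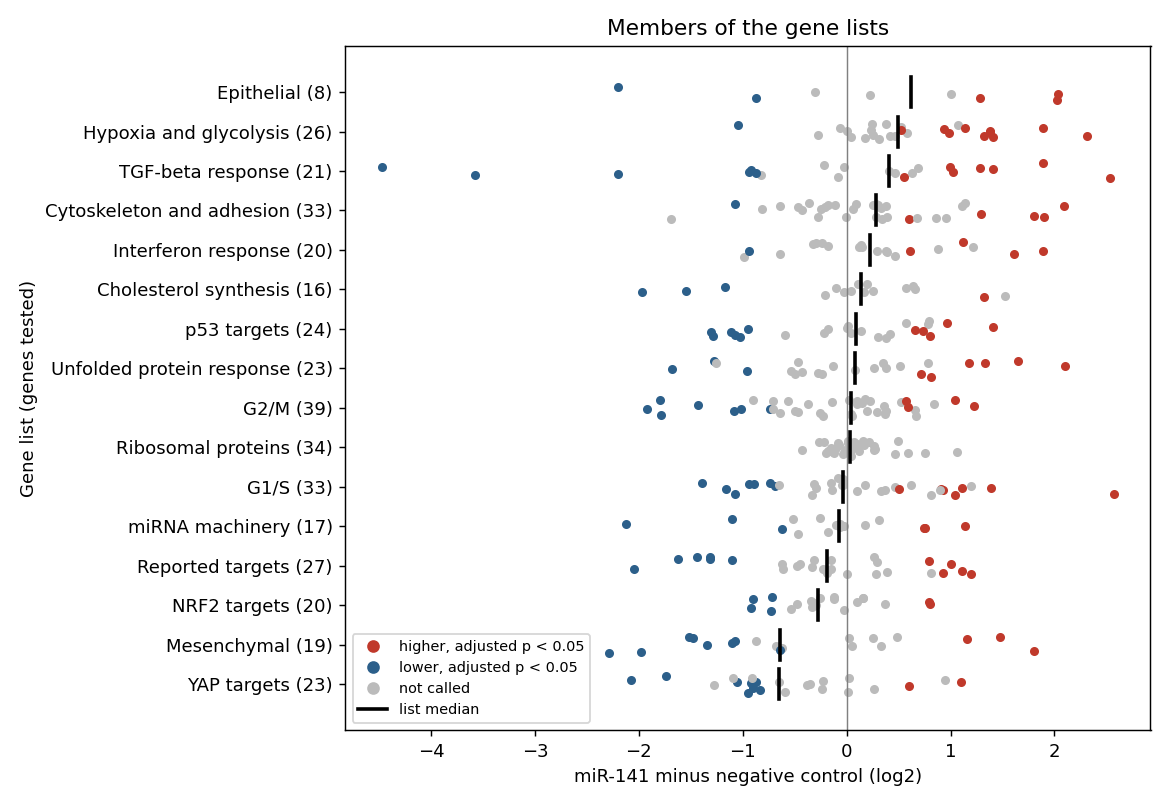
Log2 difference, miR-141 (n = 2) minus negative control (n = 3), of each tested member of 16 gene lists; points are genes, red called higher, blue called lower and gray not called, vertical shifts within a row only separate the points, and black bars are list medians. The YAP targets lie lowest with a median of −0.65, and the hypoxia and glycolysis genes have a median of 0.49 with 10 members called higher.

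Of 33 G1/S genes, 7 rose, 7 fell and 19 were not called (11 and 8 adjusted over the list alone): the transcription factor E2F2 rose by 2.57 and the replicative helicase gene MCM2 by 1.39, the cyclin gene CCNE2 (−1.40) fell, and MCM7 was at 1.19 (adjusted p = 0.091). Of 39 G2/M genes, 7 fell, 4 rose and 28 were not called (6 and 4 adjusted over the list alone). The mitotic kinesins KIF20A (−1.93) and KIF23 (−1.79), the ubiquitin-conjugating enzyme gene UBE2C (−1.79) and the spindle gene TPX2 (−1.43) fell. Of 24 p53 targets, 5 rose, 6 fell and 13 were not called (6 and 7 adjusted over the list alone), with the translesion polymerase gene POLH higher by 1.41 and PLK2 (−1.30), TIGAR (−1.29) and CCNG1 (−1.12) lower. Camera gave adjusted p-values of 0.94, 0.41 and 0.94 for the 3 lists. With the mean of all probe sets of a gene, the G2/M list had 13 lower and 2 higher members, a median of −0.28 and an adjusted p of 0.063. Without miR-141 replicate 2 the counts fell to 2 higher and 3 lower in G1/S, 0 and 4 in G2/M, and 3 lower p53 targets, 1 p53 target was higher without control replicate 3, and MCM2 (adjusted p up to 0.18), CCNE2 (0.099), TPX2 (0.074) and CCNG1 (0.058) each lost their call without at least 1 array.

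Stress and metabolic lists also held genes of both directions. In the unfolded protein response, 6 of 23 genes rose, 3 fell and 14 were not called: the mTOR inhibitor gene DDIT4 rose by 2.10, the pseudokinase TRIB3 by 1.65 and the asparagine synthetase gene ASNS by 1.33, and EDEM1, which acts in disposal of misfolded glycoproteins, fell by 1.68. Of 16 cholesterol synthesis genes, 3 fell, 1 rose and 12 were not called, with the sterol carrier STARD4 at −1.97, the squalene epoxidase gene SQLE at −1.54, the lanosterol synthase gene LSS at 1.32 and PMVK at 1.52 (adjusted p = 0.057). Of 20 NRF2 targets, 4 fell, 2 rose and 14 were not called (3 and 2 adjusted over the list alone): the thioredoxin reductase gene TXNRD1 was at −0.92, SRXN1 at 0.81, and the related but distinct aldo-keto reductases AKR1C1 (−0.91) and AKR1C3 (0.79), whose probes can cross-hybridize, went apart. Among 20 interferon-response genes, 4 rose, 1 fell and 15 were not called (3 and 0 adjusted over the list alone), with IFIT3 higher by 1.89, OAS3 by 1.61 and HERC6 by 1.12 and LGALS3BP at 1.21 (adjusted p = 0.12). Camera adjusted p-values were 0.94, 0.94, 0.27 and 0.94 in that order. Without miR-141 replicate 2, 0 cholesterol genes were lower, 1 NRF2 target was lower, 1 interferon gene was higher and 1 gene of the unfolded protein response was lower, 2 genes of that response were higher without either miR-141 array, and TXNRD1, TRIB3, EDEM1, STARD4, SQLE, SRXN1, AKR1C1, AKR1C3, OAS3 and HERC6 each lost their call without at least 1 array (adjusted p up to 0.16).

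Of 21 TGF-β response genes, 7 rose, 6 fell and 8 were not called (7 and 7 adjusted over the list alone). Besides THBS1, the homeobox repressor TGIF1 (−3.58, SE 0.23) and the receptor TGFBR2 (−2.20, SE 0.32) fell, and the collagen gene COL1A1 rose by 2.53 (SE 0.48). Of 33 cytoskeleton and adhesion genes, 5 rose, 1 fell and 27 were not called (3 and 1 adjusted over the list alone), with the phospholipase gene PLCG1 at 2.09, the tropomyosin gene TPM2 at 1.90, the integrin gene ITGA3 at 1.80 and WASF3 at −1.69 (adjusted p = 0.069). In the miRNA machinery, 3 of 17 genes rose, 3 fell and 11 were not called: the decapping genes DCP1A (−2.13) and DCP2 (−1.10) fell, the nuclease gene DROSHA rose by 0.75 and TNRC6A, a partner of Argonaute proteins, by 1.14. Other probe sets of TNRC6A were called lower, down to −3.91, and another of DCP2 was called higher by 1.30. With the mean of probe sets DCP2 lost its call (−0.28, adjusted p = 0.19), DCP1A was at −1.19 and TNRC6A was called lower (−1.28). Of 34 ribosomal protein genes, limma called 0 in either direction, and 0 had an unadjusted p under 0.05 or were called with a trend or robust estimation, with RPL18 at 1.06 (adjusted p = 0.23), RPS19 at 0.75, RPS14 at 0.59 and RPS3 at 0.49, though 2 were called higher without miR-141 replicate 2 and 1 lower without miR-141 replicate 1. Camera adjusted p-values were 0.94 for the TGF-β, cytoskeleton and ribosomal lists and 0.41 for the miRNA machinery, and the TGF-β list had a median of 0.41 but a mean of −0.11. Camera compares a list with the other genes, and the median over all tested genes was 0.15, so a list above 0 can be lower by camera. Medians lay above 0 but under 0.15, with a downward camera direction, for cholesterol synthesis (0.14), the unfolded protein response (0.08), p53 targets (0.09) and ribosomal proteins (0.03). G2/M had a median of 0.04 and a mean of −0.17 and G1/S a median of −0.03 and a mean of 0.14. With the mean of all probe sets, cytoskeleton and adhesion had 5 higher and 5 lower members (median −0.18), the unfolded protein response 5 and 5, and the miRNA machinery 2 higher and 7 lower (median −0.40). Without 1 array, higher cytoskeleton members dropped to 1 (miR-141 replicate 2 left out), higher TGF-β members to 3 (control replicate 2 or 3) and lower ones to 4 (any array but miR-141 replicate 1), and higher miRNA machinery members to 0 (control replicate 1 or 3). ITGA3 (adjusted p up to 0.23), TNRC6A (0.12), DROSHA (0.077), COL1A1 (0.057) and PLCG1 (0.052) lost their calls without at least 1 array.

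Markers of cell types other than carcinoma cells were mostly under the filter. Of 15 leukocyte markers on the array, 1 was tested, LAPTM5 (1.69, adjusted p = 0.11), whose dimmer probe set was called higher by 0.91. Among 11 fibroblast markers, COL1A1 was called and FAP was at −0.80 (adjusted p = 0.33). Of 11 endothelial markers, TIE1 rose by 1.57 (adjusted p = 0.039), while ENG (0.74) and CDH5 (−0.09) were not called. Of 11 melanocyte and neural markers, MAP2 (1.88) and MITF (1.68) rose and TUBB3 (0.47) was not called. TIE1 lost its call whichever array was left out (adjusted p up to 0.16) and MITF without either miR-141 array (up to 0.088).

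Probe sets of the same gene often disagreed. RBBP4, at −4.07 on its brightest probe set, was called higher by 2.00 on another, THBS1 was called higher by 2.40 on another, and EIF4G1 had another at 1.20 that was not called. HNRNPL (−6.63 on another probe set), ALYREF (−4.73), SCEL (2.42), KIFC2 (2.86) and GLI4 (2.33) kept their direction, and TRIO had others from −4.37 to −0.03. Among the largest decreases, MYC, SNRNP40, CXCL8, CD9, PRPF39, MIX23, EEIG2, MOB4 and DCAF17 had no other tested probe set. Among the largest increases, the same held for PSMC3, GIT1, MCOLN3, FOXH1, HGS, SEMA3F, SUV39H1, POLM and SPECC1L. The differences of these genes therefore could not be checked on another probe set. Of 16337 probe sets tested, 3117 were called higher and 3274 lower. Among 1011 genes with at least 2 called probe sets, 269 (26.6%) had calls in both directions. Across 3556 genes, which are not independent replicates, the differences of the 2 brightest probe sets correlated at 0.36 and 63.1% had the same sign.

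**Figure D3:**
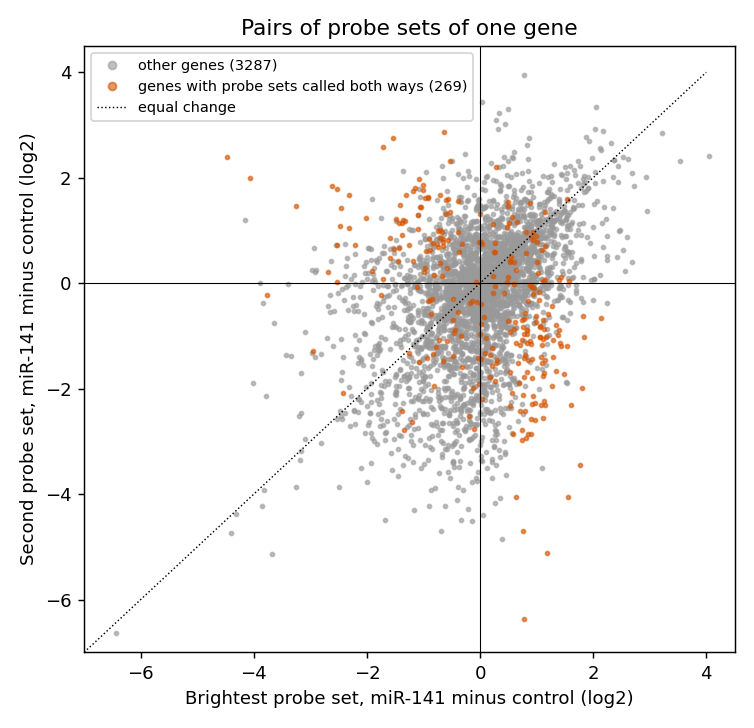
Log2 difference, miR-141 (n = 2) minus negative control (n = 3), of the brightest (horizontal axis) against the next brightest probe set (vertical axis) of 3556 genes; each point is a gene, orange for the 269 genes with probe sets called in opposite directions among all their probe sets. The correlation across genes is 0.36, and many points lie far from the dotted line of equal change.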

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

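With groups of 2 and 3 arrays, no array was tested as an outlier, and the single comparison leaves no second effect to set against it. Estimated array weights were 0.71 for control replicate 2, against 2.12 and 1.84 for control replicates 1 and 3. Both miR-141 arrays had 0.60, since 2 arrays cannot be told apart in this way. The values below come from probe sets outside the gene test whose miR-141 mean lay above every control array, or that were called higher. The GAPDH control probe sets were higher with miR-141 by 0.20 at the 3′ end, 1.86 in the middle and 3.32 at the 5′ end, with overlapping arrays in each case. The 5′ value came from miR-141 replicate 1 alone, at 10.1, against 3.42 on miR-141 replicate 2 and 2.78 to 3.93 on the controls. The ACTB control probe sets, given for comparison, were lower by 0.42 (3′) and 2.02 (middle) without overlap. The middle gap was narrow, with miR-141 replicate 1 at 7.26 and control replicate 1 at 7.29. The 5′ ACTB set, under log2 4 on all arrays, was higher by 0.34 with overlap. Of 2002 tested probe sets with no single gene name, 436 were called higher and 398 lower.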

How the results depend on the processing

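The setting without genes of opposite probe sets was added after seeing the data, and the other settings were planned. Over all settings, named genes kept their direction in 1488 of 1493 values. The filter settings, both eBayes variants and the setting without genes of opposite probe sets keep each gene's probe set and difference. Direction could not change there, so much of this agreement was fixed in advance. Most named genes were also picked for large differences on these same arrays. Among the calls of 3326 genes, none changed sign in any refit by gene except the mean of probe sets, where 140 did. The count of genes changed was 6391 per probe set (more features tested) and 2181 with a minimum difference of 1 (a subset by construction), and ran from 1476 to 2283 without 1 array (fewer arrays, though the cause was not tested further). Of 101 named genes, 85 were called, and 53 to 77 without 1 array: 46 of the 85 kept their call in all 5 such fits. Camera called 2 lists, 0 under the stricter filter, 0 with an estimated correlation and 1 to 2 without 1 control array. The estimated form lowers the degrees of freedom, so its loss of calls does not show that correlation between genes made the lists pass. For the YAP targets the estimated correlation (−0.00085) was under the preset 0.01, yet the unadjusted camera p went from 0.0010 to 0.036. The cause of the other losses was not tested. With the mean of probe sets, FBN1 went to −0.091 and TNRC6A to −1.28, since their other probe sets were lower, and the falls of THBS1 (−0.77), RBBP4 (−0.72), EIF4G1 (−1.47) and DCP2 (−0.28, no longer called) shrank, since other probe sets were higher. Calls gained without miR-141 replicate 1 included FJX1 (−2.13), WASF3 (−2.57) and FAP (−1.87), and LAPTM5 (2.86) was gained without miR-141 replicate 2. Without 1 array, RPS14 ran from −0.30 to 1.49, FAP from −1.87 to 0.27 and CDH5 from −0.47 to 0.30, none called with all 5 arrays. Over the alternatives the adjusted p of the YAP targets ran from 0.0005 to 0.42, of the hypoxia list from 0.0017 to 0.42 and of the mesenchymal list from 0.027 to 0.42. The mesenchymal list passed with the mean of probe sets (adjusted p = 0.027) and without genes of opposite probe sets (0.029). Signs of list medians below are set against 0, while the median over all tested genes was 0.15 in the main fit. Medians of lists that camera did not call in the main fit changed sign with no filter (mesenchymal 0.035, TGF-β −0.03), under the stricter filter (unfolded protein response −0.27), with the mean of probe sets (G2/M −0.28, cytoskeleton −0.18, ribosomal −0.03), with quantile normalization (interferon −0.02, G1/S 0.07, unfolded protein response −0.08), with centring (G2/M −0.01, ribosomal −0.03) and without genes of opposite probe sets (unfolded protein response −0.03). G1/S also turned with array weights (0.04), the block (0.01) and without 1 array (up to 0.09, and 0.00 without miR-141 replicate 2), and ribosomal proteins without miR-141 replicate 1 (−0.01). The only shared replicate numbers were 1 and 2, and same-numbered arrays deviated apart (r = −0.21 and −0.06). The deviations of the 2 miR-141 arrays mirror each other, so these are not separate checks. They cannot decide whether the numbers pair the samples. The control labels name these arrays as analysed with miR-141 and give replicate numbers, but state no pairs. With a replicate block 1583 genes were called. Control replicate 3 shares its number with no miR-141 array, so the block takes it out of the group difference. The block therefore gives the same differences as the fit without control replicate 3 and is not a separate check on them. Gene counts under the other settings ran from 2619 to 4280, the reported targets' median from −0.26 to −0.13. Camera with robust estimation and the seed site test with its alternatives were not run. Signal over background limits the genes under log2 4 in a group, 134 called genes with miR-141 and 316 in the controls.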

Other observations

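The families here and the tests of the chance split, of one-way calls, of transcript position, of the 18S control and of YAP1 were chosen after the results were seen. Of 26 gene families and classes, the CXC chemokines stood out: all 4 tested members fell, CXCL8 at −5.63, CXCL2 at −2.31, CXCL1 at −2.19 and CXCL3 at −1.98 (camera adjusted p = 0.0061, and adjusted p = 0.67 with an estimated correlation). All 4 stayed called under both scalings, and without either miR-141 array, and 3 of 4 with any 1 control array left out. CXCL1, CXCL2 and CXCL3 are close paralogs whose probes can cross-hybridize. The 12 DUSP phosphatase genes went both ways, 4 higher and 5 lower (adjusted p = 0.62), with DUSP1 at −3.50 and DUSP10 at −2.95 and DUSP28 at 2.43 and DUSP6 at 1.05, all called. Without 1 array the counts fell to 2 higher (miR-141 replicate 1 left out) and to 2 lower (miR-141 replicate 2).

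Laminin and collagen genes showed more increases than decreases without passing as families. Of 7 laminin chains, 5 rose, with LAMA5 at 2.61, LAMB2 at 1.68, LAMA4 at 1.53 and LAMB3 at 1.47, and LAMC1 fell by 1.44. Of 12 collagen chains, 6 rose, among them COL18A1 (2.53) and COL6A2 (2.16), and 2 fell. The adjusted p was 0.18 for both, with the same counts under both scalings, and 3 laminins were higher without miR-141 replicate 1 or control replicate 2. No collagen was lower without miR-141 replicate 2 or control replicate 2 or 3, and 1 was without either of the other arrays. Of 11 histone genes, 5 fell, with H3-3A at −3.53 and H2AC6 at −2.16, and 1 rose (adjusted p = 0.064), with 2 lower without control replicate 2 or 3, and probes for histone genes can cross between copies. Long non-coding RNA genes were higher in 73 and lower in 29 of 210, with a median of 0.50 (camera adjusted p = 0.064, and 0.68 with an estimated correlation). After quantile normalization 63 were higher and 41 lower (camera adjusted p = 0.22), and without control replicate 2, 44 and 16. The median was 0.42 without miR-141 replicate 2 and 0.58 without miR-141 replicate 1.

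The pattern that most bears on the gene values is that 269 genes had probe sets called in opposite directions. Wrong calls at the nominal rate of 5% are argued against, since 1000 simulations in which each gene moved one way and 5% of calls took a random sign gave at most 76 such genes, while shuffled signs gave at least 520. A higher rate of wrong calls was not simulated and stays open. Weaker hybridization is argued against by control replicate 3, whose spike-in controls lay at 0.65 of the way to the miR-141 arrays while the probe sets of such genes, called without that array, lay at a median of 0.030 (245 probe sets of 108 genes). A uniform shift along the transcript stays open: the group difference in middle minus 3′ signal was −1.60 for ACTB and 1.67 for GAPDH, a range of 3.26, but the arrays of the groups overlapped in both. A difference in amplification between the groups and a change in transcript ends or isoforms with miR-141 cannot be told apart, because the 18S difference of −2.42 (28S middle −0.48 with overlap) coincides with the treatment and no label groups the arrays in another way. The 28S 5′ set (−1.07 without overlap) was under log2 4 on all arrays. Its difference rested mostly on control replicate 1, at 3.68 against 1.39 and 1.41 on the other controls.

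The lower YAP target list may depend on the choice of probe set, since averaging all probe sets moved its adjusted p from 0.016 to 0.072, although its median hardly moved (−0.65 to −0.64). A candidate explanation in which lower YAP1 lowers its targets was not decided: the brightest YAP1 probe set was at −2.04 and another at 0.030, which leaves the change in YAP1 itself open. For the higher hypoxia and glycolysis list, the choice of probe set is argued against, because the adjusted p was 0.039 with all probe sets averaged and 0.037 without. Its call still ended without miR-141 replicate 1 (adjusted p = 0.093), so an effect of that culture or array stays open. The labels give no difference between groups in medium, density or oxygen, and no biological explanation of this list was tested.

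With 2 arrays against 3 there are 10 splits of the 5 arrays, too few for a share under 0.05. The real split gave 3326 called genes, and it was the 1 split with as many, since the highest of the others was 0 by limma, with up to 661 genes at an unadjusted p under 0.05. Every other split mixes miR-141 and control arrays in a group, so the real difference widens its spread. Few calls are expected there whatever caused that difference, so the splits cannot tell treatment from a batch.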
